A study of Mus musculus with 10 samples.

How the data were processed

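Livers of mice kept on a high-fat diet were profiled by RNA sequencing. Per the labels, RNA was enriched for poly(A) tails, libraries did not keep strand, sequencing was done on the BGI DNBSEQ platform, and RNA integrity numbers lay between 6.6 and 8.5. The weekly feeding cycle reduced calories by 50% on days 1 and 4 and by 70% on days 2 and 3, with free feeding on days 5 to 7. The 10 samples were grouped by their labels as ad libitum controls (AL, n = 3), day 3 of the cycle (LC, n = 4) and day 7 of the cycle (RF, n = 3). The labels do not state that the samples are separate animals, so the p-values measure the spread between these samples. The time of day and the feeding state at collection, and the sex of the mice, are not given in the sources used here.

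The authors deposited a gene table with 2 units for each sample. The deposited expected counts are estimated counts that need not be whole, and 10.9% of their values were not whole. The deposited FPKM values are fragments scaled by transcript length and by sequencing depth. HISAT and Bowtie2, with no version or role, and the genome build GRCm39 are named per the submitters' processing notes. Which program made the counts, and from which gene annotation, is not given in the sources used here. Estimated counts share reads between near-identical genes by a model, so members of the Mup, Cyp2a, Cyp2b, Cyp4a, Ugt1a, Gsta, Saa and Scd families are less certain than single-copy genes. Without strand, overlapping genes on opposite strands cannot be told apart.

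The table had 17359 genes, keyed by NCBI gene number and symbol, of which 253 had no count in any library and none was encoded in the mitochondrial genome. Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 12789, and libraries were scaled by the trimmed mean of M values (TMM). A model with a mean for each group was fitted to all 10 libraries with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust), and the 3 comparisons were tested with its quasi-likelihood F test. Genes with a Benjamini-Hochberg adjusted p below 0.05 over all genes tested were called changed. Standard errors of log2 fold changes were computed as the absolute fold change over the square root of F. Levels are CPM, counts scaled to an equal library total, with TMM factors, as mean ± SD.

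Lists of genes were fixed for 32 liver functions and 13 cell types. They were tested with camera in limma 3.58.1, at a preset correlation between genes of 0.01, and adjusted over the 42 lists with at least 4 measured members. The preset correlation is an assumption, so each list call is given with its adjusted p from a correlation estimated for that list. In none of the 3 comparisons did a list call hold with the estimated correlation. The number of members that passed is given over all genes tested and adjusted over the list alone. The lists, the model, the tests, the rule for named genes and the alternatives were fixed before the data were examined, except for alternatives and tests said below to have been added.

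Genes were named by a rule. For each comparison it took the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out symbols that are only a clone or model number. It also took the 2 to 4 members with the smallest p of each list described, a fixed set of core genes of liver metabolism with their values whether or not they passed, and the 5 kept and 5 returned genes with the largest change. Some genes that the rule took are not reported here. A gene called at LC against AL was counted as kept where it was also called, in the same direction, at RF against AL. It was counted as returned where it was called in the opposite direction at RF against LC.

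The same steps were tested on simulated counts with known changes. In the simulation of LC against AL, 4.48% of genes changed by 0.5 on the log2 scale were recovered, 62.7% of those changed by 1 and 92.4% of those changed by 2. For RF against AL the shares were 7.46%, 58.2% and 90.9%, and for RF against LC they were 5.97%, 62.7% and 83.3%. Between 5 and 8 unchanged genes were called in each. Only 66 or 67 genes were changed at each size, far fewer than were called in the real LC against AL or RF against LC. The Benjamini-Hochberg adjustment is stricter where fewer genes change, so these shares are not the sensitivity of those comparisons. Both lists shifted by 0.6 were recovered in each comparison, and of the 40 other lists 1 was called at RF against AL. Kept and returned genes were simulated only with a log2 change of 2 and a mean above 5 CPM. Of these, 98 of 100 kept genes and 99 of 100 returned genes were recovered, and smaller changes were not tried.

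Library totals lay between 13871500 and 15899500 counts. The alternatives tried were DESeq2 1.42.0, size factors by relative log expression, library totals with no further scaling, 2 other filters on low counts, the compared groups alone, replicate number as a block, limma voom with sample quality weights, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1), stricter thresholds, other list tests, and leaving out each library in turn. The removal of trends on gene length and GC content, and the omission of the 50 most abundant genes with library totals in place of TMM, were added after the data were seen. Gene length was taken from the ratio of the deposited count to FPKM, and GC content from transcripts of GENCODE M21, which is built on GRCm38 and was used for names and GC content only. No coordinates are given, because the annotation behind the counts is not named in the sources used here.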

Results

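The series followed the liver of mice fed a high-fat diet through a weekly cycle of calorie restriction and refeeding. Liver RNA was sequenced from ad libitum controls (AL, n = 3), from the restricted phase at day 3, when intake was reduced by 70% (LC, n = 4), and from the refeeding phase at day 7, after free feeding had resumed (RF, n = 3). Totals per library were 14179700 to 15899500 expected counts at AL, 13871500 to 15801500 at LC and 14601700 to 15502200 at RF. The 4 LC libraries lay apart from the other 6 on the first principal component of log2 CPM, at 27.1 to 44.5, against −37.5 to −11.1 at AL and −25.1 to −16.1 at RF. AL replicate 2 was the AL library nearest to LC, at −11.1. Across genes, which are not independent replicates, Pearson's r between libraries was 0.975 to 0.985 within AL, 0.973 to 0.982 within LC, 0.947 to 0.970 between AL and LC, and 0.973 to 0.982 between AL and RF. The 10 most abundant genes took 18.6 ± 1.74% of counts at AL (SD, n = 3), 14.9 ± 0.288% at LC (n = 4) and 17.2 ± 1.32% at RF (n = 3). Major urinary protein genes took 9.37 ± 2.12%, 5.99 ± 1.86% and 9.46 ± 1.76% of counts in the same order.

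**Figure D1:**
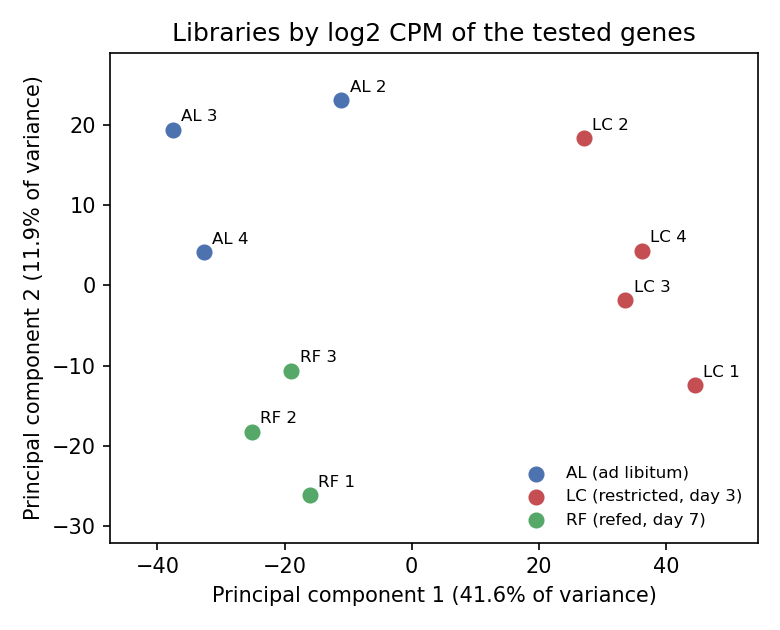
Each point is a library, placed by principal components 1 (41.6% of variance) and 2 (11.9%) of log2 CPM of the 12789 genes tested, and coloured by group (AL ad libitum, LC restricted at day 3, RF refed at day 7). The 4 LC libraries sit at 27.1 to 44.5 on component 1, and the AL and RF libraries at −37.5 to −11.1.

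The comparison of LC with AL asked what restriction changed in the liver of mice on the same high-fat diet. Of the lists tested, 21 were lower at LC, among them fatty acid synthesis (8 of 22 genes fell), amino acid catabolism (19 of 35), chaperones of the endoplasmic reticulum (13 of 20) and acute phase proteins (12 of 23), and 1 was higher, sinusoidal endothelium (5 of 14 rose). None of these list calls held with an estimated correlation. The largest fall among the named genes was that of Scd1 (NCBI gene 20249), the stearoyl-CoA desaturase that makes monounsaturated fatty acids. Its level was 5295 ± 1789 CPM at AL (SD, n = 3) and 238 ± 109 CPM at LC (n = 4), a log2 fold change of −4.48 (SE 0.44, adjusted p = 0.00031). In all, 4034 genes (31.5%) were called by edgeR's quasi-likelihood test, 2045 higher and 1989 lower at LC, and 486 and 332 of them changed at least 2-fold. The split depended on the scaling. Size factors by relative log expression gave 1896 higher and 2123 lower, and DESeq2 1938 and 2249. With library totals alone the median of all genes moved up by 0.31 on the log2 scale, and 4395 genes were called higher and 686 lower (86.5% higher, against 50.7%), and log2(FPKM + 1) gave 4291 and 708. Without AL replicate 3 the counts were 959 higher and 1151 lower, and without AL replicate 4 the count higher was 1196.

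The 5 further largest falls were those of Cfd, which encodes complement factor D, Ugt1a5, the water channel gene Aqp8, the lipogenic regulator Thrsp and the steroid hydroxylase gene Cyp17a1. Cfd (NCBI gene 11537) was at 101 ± 47.2 CPM at AL and 8.77 ± 7.26 CPM at LC, a log2 fold change of −3.53 (SE 0.66, adjusted p = 0.0055). The log2 fold changes of the others were −3.14 for Ugt1a5, −2.75 for Aqp8, −2.74 for Thrsp and −2.72 for Cyp17a1. The largest rises were those of the cytochrome P450 genes Cyp2b9 (2.52) and Cyp2j9 (2.41), the sialyltransferase gene St6galnac3 (2.15), Mup8 (2.14), the Polycomb gene Pcgf2 (2.12) and the metalloprotease gene Adamts7 (2.06). Cyp2j9 (NCBI gene 74519) was at 28.8 ± 17.6 CPM at AL and 153 ± 51.4 CPM at LC (SE 0.41, adjusted p = 0.0030). Reads of Ugt1a5, Cyp2b9 and Mup8 may be shared with near-identical genes. Mup8 was at 95.6 CPM in LC replicate 4 and at 13.4 to 30.7 CPM in the other LC libraries. Ugt1a5 and Aqp8 lost their calls without AL replicate 4 (adjusted p = 0.059 and 0.058). Cyp2b9 lost its call without AL replicate 2 or 4, LC replicate 3, or RF replicate 1 or 3 (0.050 to 0.12), and Mup8 without any AL or RF replicate or LC replicate 2 (0.069 to 0.15).

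Of the 22 fatty acid synthesis genes measured, 8 fell, 1 rose and 13 did not pass (10 fell and 1 rose adjusted over the list alone), with a median log2 fold change of −0.63. The list was lower at LC (camera adjusted p = 6.8e-06, but adjusted p = 0.35 with an estimated correlation). The falls were led by Scd1, Thrsp and the desaturases of polyunsaturated fatty acids Fads1 (−1.70, SE 0.19, adjusted p = 0.00016) and Fads2 (−2.21, SE 0.22, adjusted p = 0.00014). Fasn, which encodes fatty acid synthase, was at 591 ± 124 CPM at AL and 385 ± 134 CPM at LC and did not pass (−0.62, SE 0.50, adjusted p = 0.38), nor did Srebf1, the gene of a transcription factor of lipid synthesis (−0.41, SE 0.22, adjusted p = 0.17; 0.020 with trends on length and GC content removed). Of 22 lipid droplet genes 10 fell and 1 rose (11 and 1 adjusted over the list alone; list adjusted p = 1.7e-05, and adjusted p = 0.24 with an estimated correlation). Cidec, whose product fuses droplets, was at 44.4 ± 0.294 CPM at AL and 8.61 ± 6.25 CPM at LC (−2.37, SE 0.47, adjusted p = 0.0065). Cideb (−1.22), Fitm1 (−1.22), the fatty acid transporter gene Cd36 (−1.15) and Abhd5 (−0.86), whose product activates triglyceride lipase, fell too. The gene that rose was Plin4, a droplet coat gene chosen after its values were seen, at 81.4 ± 28.1 CPM at AL and 178 ± 65.1 CPM at LC (1.13, SE 0.33, adjusted p = 0.028). Plin4 lost its call without AL replicate 3 or 4 or LC replicate 1 or 4 (0.058 to 0.083), with no filter on low counts (0.054) and with trends on length and GC content removed (0.79, adjusted p = 0.11). Of 20 cholesterol synthesis genes 3 fell and none rose (the same counts adjusted over the list alone; list adjusted p = 0.026, and adjusted p = 0.71 with an estimated correlation). That list call was lost without AL replicate 3 or 4, or LC replicate 3 or 4 (0.053 to 0.17). The medians of the droplet and cholesterol lists were −0.58 and −0.49, and with library totals alone the 3 medians were −0.33, −0.26 and −0.16 in the order given.

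Of 35 genes of the urea cycle and amino acid catabolism measured, 19 fell, 1 rose and 15 did not pass (23 and 1 adjusted over the list alone), with a median of −0.61 (list adjusted p = 7.9e-09, and adjusted p = 0.24 with an estimated correlation). Among them were Ass1, the argininosuccinate synthase gene (2407 ± 327 CPM at AL, 726 ± 184 CPM at LC, −1.73, SE 0.19, adjusted p = 0.00016), the ornithine genes Oat (−1.91) and Otc (−1.19), and Kynu of tryptophan breakdown (−1.37). Of 20 genes for chaperones of the endoplasmic reticulum and the unfolded protein response, 13 fell and none rose (13 adjusted over the list alone), with a median of −0.72 (list adjusted p = 7.9e-09, and adjusted p = 0.35 with an estimated correlation). The protein disulfide isomerase genes Pdia4 (−1.47, SE 0.16, adjusted p = 0.00016), Pdia6 (−1.23) and Pdia3 (−1.28) and the calreticulin gene Calr (−1.44) were among them. Hspa5, the gene of the main chaperone BiP, fell by 1.01 (SE 0.26, adjusted p = 0.013), a call lost without AL replicate 3 (0.067) and in the FPKM table (0.055). Of 31 proteasome genes 18 fell and none rose (21 adjusted over the list alone; list adjusted p = 3.1e-07, and adjusted p = 0.33 with an estimated correlation). Among them were Psmd14 (−1.26) and Psmb2 (−0.79). Of 50 oxidative phosphorylation genes 26 fell and none rose (27 adjusted over the list alone; list adjusted p = 1.6e-06, and adjusted p = 0.33 with an estimated correlation). Among them were Uqcrc2 (−0.93) and Ndufa10 (−0.83). The medians of the proteasome and respiratory lists were −0.38 and −0.40. Scaled by library totals alone, the medians were −0.31 for amino acid catabolism, −0.41 for chaperones, −0.07 for the proteasome and −0.09 for the respiratory list.

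Of 23 acute phase genes 12 fell and none rose (12 adjusted over the list alone), with a median of −0.81 (list adjusted p = 8.1e-07, and adjusted p = 0.24 with an estimated correlation). They included the fibrinogen genes Fga (1240 ± 330 CPM at AL, 399 ± 55.7 CPM at LC, −1.64, SE 0.18, adjusted p = 0.00016) and Fgg (−1.06) and the metalloreductase gene Steap4 (−1.34). Saa1, a serum amyloid gene, fell by 1.97 (adjusted p = 0.025), a call lost without AL replicate 2 (0.071) or LC replicate 1 (0.066). Of 18 genes known to be higher in male mouse liver, 8 fell and none rose (8 fell and 1 rose adjusted over the list alone; list adjusted p = 0.0021, and adjusted p = 0.35 with an estimated correlation). Among them were Mup20 (−1.07), Cyp4a12a (−1.08) and Nudt7 (−1.02), the first 2 of which have close copies. Of 11 measured genes known to be higher in female mouse liver 3 rose and 1 fell (3 and 1 adjusted over the list alone). The female-biased list was not called (median 0.29, camera adjusted p = 0.96). Of 24 cell cycle genes 11 fell and none rose (13 adjusted over the list alone; list adjusted p = 0.0016, and adjusted p = 0.47 with an estimated correlation). Among them were the replication genes Pcna (29.2 ± 5.12 to 16.4 ± 2.59 CPM, −0.83) and Mcm2 (−1.40), and the low-count gene Mki67 (3.45 ± 1.45 to 1.15 ± 0.515 CPM, −1.57), which lost its call without AL replicate 4 (0.053). Of 26 genes of glycolysis and glycogen 12 fell and 3 rose (13 and 3 adjusted over the list alone; list adjusted p = 0.024, and adjusted p = 0.43 with an estimated correlation). Gapdh (−1.14) and Pgam1 (−0.99) fell and Pfkfb3, whose product raises glycolytic flux, rose (1.01), and the list call was lost without AL replicate 4 (0.052). With library totals alone the medians were −0.50 for acute phase, −0.50 for male-biased, −0.46 for cell cycle and −0.15 for glycolytic genes, against −0.81, −0.80, −0.76 and −0.47 with TMM.

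Core genes of fasting did not pass at day 3. Fgf21, a hormone gene induced by fasting, was at 7.53 ± 2.95 CPM at AL and 14.6 ± 7.77 CPM at LC (0.95, SE 0.47, adjusted p = 0.15). The pyruvate dehydrogenase kinase gene Pdk4 (0.02, SE 0.62), the mitochondrial carnitine transferase gene Cpt1a (−0.39, SE 0.18), Angptl4 (−0.11, SE 0.15) and Igfbp1 (0.06, SE 0.47) had adjusted p of 0.11 to 0.98. Pdk4 was at 78.4 CPM in LC replicate 1 and 422 to 450 CPM in the other LC libraries. The gluconeogenic genes Pck1 (−0.15, SE 0.20, adjusted p = 0.58) and G6pc (0.52, SE 0.23, adjusted p = 0.10), Igf1 (−0.03), Asns (−0.74), Arntl (−0.74) and Cyp7a1 (−0.35), the rate-limiting enzyme gene of bile acid synthesis, did not pass. Leaving out LC replicate 2 gave calls for Fgf21 (0.0080), Cpt1a (0.014) and G6pc (0.040). G6pc was also called with library totals alone (0.86, adjusted p = 0.011), and with both FPKM offsets (0.016), and Cpt1a with voom and sample weights (0.016) and with trends on length and GC content removed (0.034). Of 19 genes of ketogenesis and fasting-induced targets of the receptor PPARA, 7 fell and none rose (7 adjusted over the list alone; list adjusted p = 0.0037, and adjusted p = 0.43 with an estimated correlation). Those with the smallest p were Fabp1, a fatty acid binding protein gene (−0.90), Cd36 and the thiolase gene Acat1 (−0.68). Of 21 genes of mitochondrial fatty acid oxidation 6 fell and none rose (6 adjusted over the list alone; list adjusted p = 0.0022, and adjusted p = 0.47 with an estimated correlation). Among them were Eci1 (−0.99) and Acads (−0.87). The medians of these lists were −0.37 and −0.34, and −0.08 and −0.03 with library totals alone.

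Of 20 clock genes 6 rose and none fell (6 adjusted over the list alone), and the list was not called (adjusted p = 0.13). Tef, a transcription factor gene driven by the clock, was at 317 ± 48.5 CPM at AL and 642 ± 76.7 CPM at LC (1.02, SE 0.17, adjusted p = 0.00090), and Per3 (0.85), Per2 (0.67) and Per1 (0.89, SE 0.26, adjusted p = 0.022) rose as well. Per1 lost its call without AL replicate 3 (0.086), AL replicate 4 (0.095) or LC replicate 1 (0.053), and with trends on length and GC content removed (0.15). Among cell type markers, 9 of 15 hepatocyte genes fell and none rose (9 adjusted over the list alone), with a median of −0.49 (list adjusted p = 0.00043, and adjusted p = 0.24 with an estimated correlation). That median was −0.18 with library totals alone. Of 14 markers of sinusoidal endothelium 5 rose and none fell (5 adjusted over the list alone), with a median of 0.27, or 0.59 with library totals alone (list adjusted p = 0.030, and adjusted p = 0.36 with an estimated correlation). They included the scavenger receptor genes Stab2 (44.5 ± 5.66 to 86.0 ± 7.96 CPM, 0.95) and Stab1 (0.84) and Kdr, a receptor gene for vascular endothelial growth factor (0.71). The endothelial list call was lost without AL replicate 2 (0.14) or LC replicate 3 (0.052). Of 16 markers of Kupffer cells and macrophages 3 fell and none rose (2 adjusted over the list alone). Mpeg1 (−1.03) and Lyz2 (−1.42) were among those that fell. The list was not called (median −0.44, or −0.13 with library totals alone; adjusted p = 0.13).

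**Figure D2:**
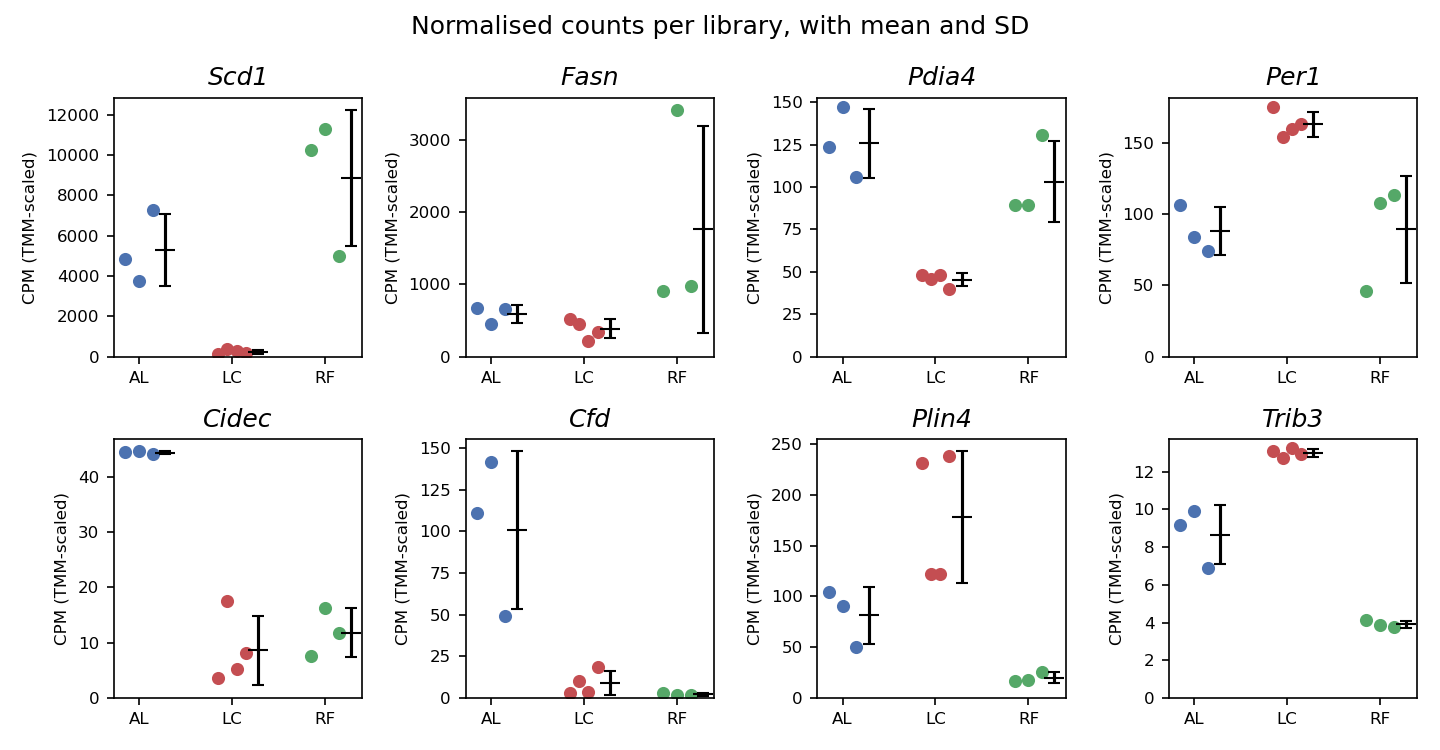
Points are libraries, by group (AL ad libitum, LC restricted at day 3, RF refed at day 7), in TMM-scaled CPM on linear axes from 0, and bars are the group mean and SD (n = 3, 4 and 3) for Scd1, Fasn, Pdia4, Per1, Cidec, Cfd, Plin4 and Trib3. Scd1 averages 238 CPM at LC against 5295 CPM at AL and 8862 CPM at RF, and Fasn reaches 3416 CPM in RF replicate 2 against 901 and 972 CPM in the other RF libraries.

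The comparison of RF with AL asked whether the refed liver at day 7 differed from that of mice never restricted. Few single genes passed. The keratin gene Krt23 was lower, at 16.8 ± 6.04 CPM at AL (SD, n = 3) and 3.08 ± 0.336 CPM at RF (n = 3), a log2 fold change of −2.44 (SE 0.36, adjusted p = 0.034). The glutathione transferase gene Gsta2 (−1.39), the tropomyosin gene Tpm2 (−1.27), the pseudokinase gene Trib3, which is induced by stress (−1.15), and the galectin gene Lgals1 (−1.03) also fell. Asap2, which encodes a regulator of Arf proteins, rose from 8.81 ± 1.39 to 19.3 ± 3.07 CPM (1.13, SE 0.17, adjusted p = 0.034). The unnamed gene Gm52512 rose from 4.73 ± 0.584 to 29.1 ± 3.11 CPM (2.62, SE 0.23, adjusted p = 0.00023); it lies outside the naming rule and was chosen after its values were seen. These 2 higher and 5 lower genes were all that edgeR called of 12789, with 1381 at an unadjusted p below 0.05. DESeq2 called 39 higher and 61 lower, and limma voom with sample weights 20 and 30. With library totals alone 4 were higher and 1 lower, a median shift of all genes of 0.11, and with trends on length and GC content removed none was called. Gm52512 had no value there, and the other 6 had adjusted p of 0.060 to 0.083 at log2 fold changes of −2.40 for Krt23, −1.26 for Gsta2, −1.26 for Tpm2, −1.17 for Trib3, −0.92 for Lgals1 and 0.98 for Asap2. No gene was called lower without AL replicate 3, LC replicate 3 or 4, or RF replicate 1 or 2, 3 were without AL replicate 4 and 10 without LC replicate 2. The count higher was 4 without AL replicate 2 or RF replicate 3, and 1 without AL replicate 3 or 4, LC replicate 3 or 4, or RF replicate 1 or 2.

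As lists, genes of lipid synthesis were higher at RF than at AL with none of their members past the test over all genes. Fatty acid synthesis had a median of 0.43 over 22 genes (2 rose and none fell adjusted over the list alone; list adjusted p = 8.2e-05, and adjusted p = 0.34 with an estimated correlation). Pnpla3, a lipase-family gene (1.27 ± 0.649 to 8.08 ± 6.39 CPM, 2.64, SE 0.67, adjusted p = 0.24), Acaca, the acetyl-CoA carboxylase gene (0.76, SE 0.21, adjusted p = 0.25), Fasn (1.58, SE 0.55, adjusted p = 0.37) and Scd1 (0.74, SE 0.43, adjusted p = 0.58) did not pass. Pnpla3 was called without RF replicate 3 (0.0063) and by DESeq2 (0.0026). Fasn was at 3416 CPM in RF replicate 2 and at 901 and 972 CPM in the other RF libraries. Cholesterol synthesis had a median of 0.60 over 20 genes (none passed adjusted over the list alone; list adjusted p = 0.00021, and adjusted p = 0.52 with an estimated correlation), with Pmvk at 1.30 and Lss at 0.75, and its call was lost without AL replicate 2 (0.26). Of the other core genes, Cidec was at 11.8 ± 4.36 CPM at RF against 44.4 ± 0.294 CPM at AL (−1.91, SE 0.51, adjusted p = 0.27; 0.048 without LC replicate 2, 0.042 with the 2 groups alone and 0.037 with voom and sample weights), and Angptl4 at 299 ± 48.4 against 481 ± 47.0 CPM (−0.69, SE 0.17, adjusted p = 0.21; 0.013 by DESeq2). The adjusted p of Srebf1, Cyp7a1, Pck1, G6pc, Fgf21, Pdk4, Cpt1a, Igfbp1, Igf1, Per1, Arntl, Hspa5, Asns, Saa1 and Cyp2b9 lay between 0.44 and 1.00.

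Lists of fatty acid oxidation and of lipid droplets were lower at RF than at AL. Peroxisomal and omega oxidation had a median of −0.38 over 20 genes (none called, 3 fell adjusted over the list alone; list adjusted p = 5.9e-10, and adjusted p = 0.23 with an estimated correlation). Cyp4a10 was at 1008 ± 299 CPM at AL and 456 ± 95.3 CPM at RF (−1.15, SE 0.22, adjusted p = 0.10; 0.039 without AL replicate 2, 0.046 with no filter on low counts, 0.022 with voom and sample weights and 0.00034 by DESeq2). Acot4 was at −0.80 (0.0041 by DESeq2 and 0.036 by voom) and Cyp4a14 at −0.86 (0.013 by DESeq2), and the Cyp4a genes have close copies. Lipid droplet genes had a median of −0.28 over 22 genes (none called, 4 fell adjusted over the list alone; list adjusted p = 6.1e-06, and adjusted p = 0.23 with an estimated correlation). Plin4 was at 81.4 ± 28.1 CPM at AL and 19.9 ± 5.10 CPM at RF (−2.03, SE 0.37, adjusted p = 0.12; 3.3e-07 by DESeq2). Markers of sinusoidal endothelium were higher, with a median of 0.48 over 14 genes (none called, 9 rose adjusted over the list alone; list adjusted p = 3.6e-09, and adjusted p = 0.094 with an estimated correlation). Among them were Oit3 (0.86, SE 0.15, adjusted p = 0.063; 0.048 without LC replicate 2, 0.046 with no filter on low counts, 0.023 with voom and sample weights and 0.0011 by DESeq2) and Dnase1l3 (0.90, SE 0.22, adjusted p = 0.21; 0.045 by DESeq2). Stellate cell and fibroblast markers had a median of 0.39 over 15 genes (none passed adjusted over the list alone; list adjusted p = 2.6e-05, and adjusted p = 0.28 with an estimated correlation), with Lum at 0.93, Rgs5 at 0.63 and Colec11 at 0.39. The hepatocyte list was lower beside these, with a median of −0.22 over 15 genes (none passed adjusted over the list alone; list adjusted p = 0.0052, and adjusted p = 0.28 with an estimated correlation). Library totals alone gave medians of −0.28 for peroxisomal and omega oxidation, −0.16 for lipid droplets, 0.59 for endothelium, 0.50 for stellate cells and −0.12 for hepatocytes. In all, 6 lists were higher and 18 lower, and fry, which does not compare a list with other genes, called 1 higher, the endothelial list (adjusted p = 0.019), and 0 lower.

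The comparison of RF with LC asked how the liver changed within the cycle, from restriction to refeeding. Of the lists tested, 17 were higher at RF, among them fatty acid synthesis (14 of 22 genes rose), chaperones of the endoplasmic reticulum (12 of 20) and amino acid catabolism (14 of 35), and 1 was lower, ribosomal proteins (19 of 60 fell). None of these list calls held with an estimated correlation. Scd1 rose from 238 ± 109 CPM at LC (SD, n = 4) to 8862 ± 3369 CPM at RF (n = 3), a log2 fold change of 5.22 (SE 0.46, adjusted p = 0.00032). Plin4 fell from 178 ± 65.1 to 19.9 ± 5.10 CPM (−3.16, SE 0.37, adjusted p = 0.00095). Of 22 lipid droplet genes Plin4 alone fell and 7 rose (1 and 7 adjusted over the list alone). That list was called higher at RF (median 0.38, or 0.19 with library totals alone, camera adjusted p = 0.040, and 0.48 with an estimated correlation). The other largest rises were those of the nicotinic receptor gene Chrna4 (4.51), Ugt1a5 (3.37), Thrsp (3.31), the mitochondrial carrier gene Slc25a30 (3.28) and Acmsd of tryptophan breakdown (3.02), and among the other largest falls were those of the cholesterol hydroxylase gene Cyp46a1 (−2.34), Cyp2a22 (−2.26), Gadd45b (−2.15) and the taurine synthesis gene Csad (−2.14). In all 2821 genes (22.1%) were called by edgeR, 1452 higher and 1369 lower at RF. With library totals alone the median of all genes moved by −0.21, with 673 higher and 2724 lower (19.8% higher, against 51.5%), and log2(FPKM + 1) gave 707 and 2782. Without RF replicate 2 the counts were 792 and 643, and without RF replicate 3 they were 874 and 768. Ugt1a5, Cyp2a22 and Gadd45b lost their calls without RF replicate 1 or 2 (0.052 to 0.071), and Chrna4 without LC replicate 1, 3 or 4 or RF replicate 1 or 2 (0.056 to 0.11). Chrna4 was at 16.0 CPM in LC replicate 2 and 0.879 to 2.76 CPM in the other LC libraries, and Cyp2a22 at 56.9 CPM in LC replicate 2 and 16.5 to 18.3 CPM in the others.

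Fatty acid synthesis had the highest median of the lists tested, 1.45 over 22 genes, of which 14 rose and none fell (17 adjusted over the list alone; list adjusted p = 1.2e-13, and adjusted p = 0.48 with an estimated correlation). Fads2 rose from 285 ± 31.6 to 1552 ± 171 CPM (2.44, SE 0.22, adjusted p = 7.2e-05), and Fads1 (2.05), Thrsp and Fasn (2.19, SE 0.50, adjusted p = 0.017) rose. Srebf1 rose (0.73, adjusted p = 0.031), but lost its call without LC replicate 1, 3 or 4 or RF replicate 2 (0.063 to 0.19) and with library totals alone (0.091). Of 20 cholesterol synthesis genes 5 rose and none fell (6 adjusted over the list alone; median 1.11, list adjusted p = 3.6e-06, and adjusted p = 0.48 with an estimated correlation). Among them were Ebp (1.13), Sc5d (1.31) and Tm7sf2 (1.74). Of 35 urea cycle and amino acid genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.38, list adjusted p = 5.2e-06, and adjusted p = 0.48 with an estimated correlation). Among them were Ass1 (1.59), Oat (1.83) and Kynu (1.31). Of 20 chaperone genes of the endoplasmic reticulum 12 rose and none fell (13 adjusted over the list alone; median 0.72, list adjusted p = 5.2e-06, and adjusted p = 0.48 with an estimated correlation). Among them were Pdia4 (1.19), Pdia6 (0.81) and Hspa5 (1.06, adjusted p = 0.015; 0.061 without RF replicate 3). Of 18 male-biased genes 7 rose and none fell (10 adjusted over the list alone; median 0.89, list adjusted p = 3.4e-05, and adjusted p = 0.48 with an estimated correlation). Among them were Nudt7 (1.65), Mup20 (1.13) and Cyp4a12a (1.16). Of 24 cell cycle genes 8 rose and none fell (9 adjusted over the list alone; median 0.68, list adjusted p = 0.00040, and adjusted p = 0.48 with an estimated correlation). Among them were Mcm3 (1.24) and Mki67 (1.59). Scaling by library totals alone gave medians of 1.24 for fatty acid synthesis, 0.91 for cholesterol synthesis, 0.18 for amino acid catabolism, 0.52 for chaperones, 0.71 for male-biased genes and 0.47 for the cell cycle.

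Of 60 cytosolic ribosomal protein genes 19 fell and 1 rose (25 and 2 adjusted over the list alone), the single list called lower (median −0.22, list adjusted p = 0.00024, and adjusted p = 0.58 with an estimated correlation). These included Rps28 (−0.86), Rps27 (−0.66, not called with trends on length and GC content removed, 0.056) and Rps20 (−0.66). Of 26 interferon-stimulated genes 8 rose and none fell (9 adjusted over the list alone; median 0.42, list adjusted p = 0.00068, and adjusted p = 0.48 with an estimated correlation). Among them were Ifi47 (0.94) and Irgm1 (0.78). Of 26 genes of extracellular matrix 8 rose and none fell (9 adjusted over the list alone; median 0.57, list adjusted p = 0.0017, and adjusted p = 0.48 with an estimated correlation). Among them were Sparc (0.93), Bgn (0.68) and Dcn (0.59; adjusted p = 0.057 with library totals alone). Of 15 stellate cell and fibroblast markers 6 rose and none fell (6 adjusted over the list alone; median 0.57, list adjusted p = 0.0072, and adjusted p = 0.48 with an estimated correlation). Rgs5 was one of them (1.02). Of 15 hepatocyte markers 6 rose and none fell (7 and 1 adjusted over the list alone). That list was called higher (median 0.22, or 0.007 with library totals alone, camera adjusted p = 0.027, and 0.48 with an estimated correlation). Of 5 erythroid genes 1 rose and none fell (median 1.03, camera adjusted p = 0.034, and 0.50 with an estimated correlation). Medians with library totals alone were −0.42 for ribosomal proteins, 0.22 for interferon-stimulated genes, 0.36 for extracellular matrix and 0.36 for stellate cell markers. Of 20 clock genes 4 fell and 1 rose (4 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.13). Tef fell by 1.01 (SE 0.17, adjusted p = 0.0018) and Usp2 by 0.72, Per1 fell by 0.87 (adjusted p = 0.032) and Arntl rose (1.17, adjusted p = 0.048). Per1 lost its call without any 1 of the LC replicates (0.051 to 0.073), with the 2 groups alone (0.050) and with trends on length and GC content removed (0.084). Arntl lost its call without any LC replicate or RF replicate 2 or 3 (0.071 to 0.21), with library totals alone (0.075), with voom and sample weights (0.053), with both FPKM offsets (0.052 and 0.060) and with trends on length and GC content removed (0.058). Of the other core genes Angptl4 fell (−0.58, adjusted p = 0.019; 0.091 without RF replicate 1 and 0.073 without RF replicate 2), and Cyp7a1, Pck1, G6pc, Fgf21, Pdk4, Cpt1a, Igfbp1, Cidec, Igf1, Asns, Saa1 and Cyp2b9 had adjusted p of 0.063 to 0.95. Leaving out LC replicate 2 gave calls for Fgf21 (0.033), Cpt1a (0.030) and Cidec (0.033), and leaving out AL replicate 2 for Saa1 (0.048) and Cyp2b9 (0.050). Saa1 was also called with voom and sample weights (0.048), and Cyp2b9 with these (0.049), by DESeq2 (0.016), with library totals alone (0.040) and in the FPKM table (0.024 and 0.038).

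**Figure D3:**
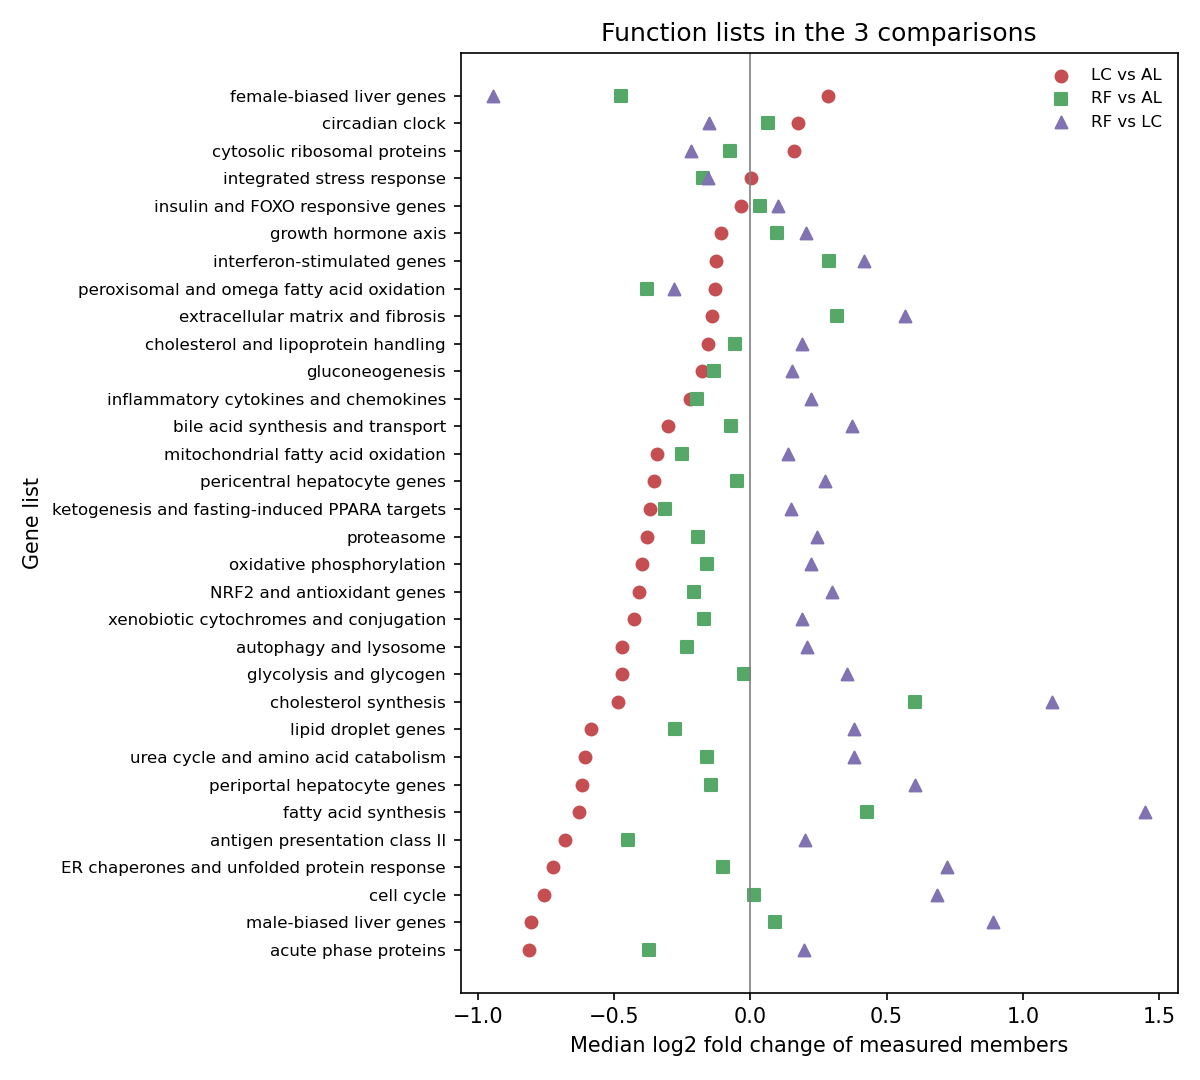
Each line is a function list, and symbols are the median log2 fold change of its measured members for LC against AL (circles), RF against AL (squares) and RF against LC (triangles), under TMM scaling. Fatty acid synthesis has medians of −0.63, 0.43 and 1.45 in that order, and the same signs with library totals alone (−0.33, 0.54 and 1.24).

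The last comparison asked whether genes changed at LC stood at the LC or the AL level once the mice were refed. Of the 4034 genes called at LC, 2215 (54.9%) returned, 1049 of them higher and 1166 lower at LC. A further 1815 were neither kept nor returned. At RF, 3958 of the 4034 (98.1%) had moved from the LC level toward or past the AL level. Both shares rest on comparisons that share the LC libraries, and a returned gene need not have reached the AL level. The 5 returned genes with the largest change were Scd1, Ugt1a5, Aqp8, Thrsp and Cyp17a1, and Cyp17a1 was at 21.6 ± 7.43 CPM at AL (SD, n = 3), 3.30 ± 1.60 CPM at LC (n = 4) and 23.8 ± 6.51 CPM at RF (n = 3). At RF against LC, Cyp17a1 rose by 2.85 on the log2 scale (SE 0.36, adjusted p = 0.0010) and Aqp8 by 2.54 (adjusted p = 0.026), the latter lost without LC replicate 1 or 3 or RF replicate 1 or 2 (0.051 to 0.10). The kept genes were 5, a count limited by the 7 genes called at RF against AL. Krt23 (−1.98 at LC and −2.44 at RF against AL), Lgals1 (−1.78 and −1.03), Gsta2 (−1.01 and −1.39) and Tpm2 (−0.91 and −1.27) were lower at both days, and Asap2 was higher (1.04 and 1.13). Lgals1 was also called at RF against LC, so it counts under both. Independent lists of these sizes would share 219 genes higher and 226 lower at LC among returned genes, and 0.320 higher and 0.778 lower among kept genes. Fold changes correlated across genes, which are not independent replicates, at r = −0.804 between LC against AL and RF against LC, which share the LC libraries, and the covariance was −0.245. Simulated groups with no effect and the same shared libraries gave −0.420 and −0.0301. With the LC libraries split, 2 for each comparison, r was −0.639 to −0.556, the covariance −0.239 to −0.223, and 812 to 1168 genes returned over the 6 splits, 24.8% to 52.8% of those called, with 2 LC libraries in each comparison. Between LC against AL and RF against AL, which share the AL libraries, r was 0.417, below the 0.546 of the simulation, and the covariance was 0.0834, above its 0.0423. The 3 AL libraries cannot be split with 2 in each part, so the part of these values that the shared controls give was not separated. Without RF replicate 2, RF replicate 3 or AL replicate 3 the returned genes were 1240, 1337 and 1474. The kept genes were 0 without AL replicate 3, LC replicate 3, or RF replicate 1 or 2, 1 without LC replicate 4, 2 without AL replicate 4, 9 without AL replicate 2 and 10 without LC replicate 2, and DESeq2 gave 60.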

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

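The tests of hepatocyte share, of Cfd and Cidec, and of length, GC content or abundant transcripts as the whole cause were chosen only after the results they measure were seen, as were the removal of these trends and the omission of the 50 most abundant genes as alternatives.

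In 4 of 135 results tested, 1 LC library stood apart from the other 3, with a gap to the nearest of them, divided by the range of the group, above Dixon's 95% critical value. Only LC was tested, because the rule needed at least 4 samples and AL and RF had n = 3 each. Chance gives about 1 in 20. Pdk4 was low in LC replicate 1 (78.4 CPM against 422 to 450, ratio 0.924), and Acat1 was high in LC replicate 4 (316 CPM against 291 to 294, ratio 0.868). In the untested RF group Pdk4 was also low in replicate 1 (115 CPM against 392 and 427). In LC replicate 2, Chrna4 (16.0 CPM against 0.879 to 2.76, ratio 0.875) and Cyp2a22 (56.9 CPM against 16.5 to 18.3, ratio 0.955) were high.

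Some results went opposite ways at LC and at RF relative to AL. They were picked by a rule that required a call in all 3 comparisons, RF against LC among them. The p-values of RF against LC below were thus part of the choice and give no separate support. Trib3 was higher at LC (0.59 on the log2 scale) and lower at RF (−1.15), and RF differed from LC by −1.73 (SE 0.17, adjusted p = 9.0e-05). The fatty acid synthesis list had medians of −0.63 at LC and 0.43 at RF, with a median difference of 1.45 (list adjusted p = 1.2e-13, and adjusted p = 0.48 with an estimated correlation). The cholesterol synthesis list had medians of −0.49 and 0.60, with a difference of 1.11 (list adjusted p = 3.6e-06, and adjusted p = 0.48 with an estimated correlation). Its list tests against AL had adjusted p of 0.71 at LC and 0.52 at RF with an estimated correlation. The LC call was lost without AL replicate 3 or 4, or LC replicate 3 or 4, and the RF call without AL replicate 2.

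The number of genes that differed between LC and AL, 31.5% of those tested, may stem from restriction, from a change in cell types or from technical trends. Of the 35 splits of the 7 samples 1, the real one, called as many genes (4034 against at most 756), which argues against chance. With 35 splits no smaller share was possible, and the labels do not state that the samples are separate animals. With trends on length and GC content removed 69.6% of the calls stayed. With the 50 most abundant genes left out and library totals in place of TMM 79.0% stayed, against 67.7% with library totals and all genes. Both tests fell between the bounds set before. The second share also reflects the loss of TMM, so it cannot measure the part of abundant transcripts. What part length and GC trends or abundant transcripts account for stays open. With these corrections 3345 and 4266 genes were still called, more than in any other split. The other splits were run without the corrections, and the corrections need not remove the whole of either effect. The counts therefore do not exclude either as the whole cause. A lower share of hepatocytes alone would raise markers of the other cell types alike. The endothelial and Kupffer cell medians (0.27 and −0.44) differed by 0.707, so these lists did not move alike. The SE of that difference, 0.257, was over marker genes, not samples. A lower share beside a separate fall of Kupffer cell markers would give the same, so the test cannot decide. Other medians were −0.49 for hepatocytes, 0.29 for cholangiocytes and −0.12 for stellate cells. A lower hepatocyte share, restriction itself and a change in endothelial cells stay open.

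Cfd and Cidec were low at both days of the cycle, at 101 ± 47.2, 8.77 ± 7.26 and 2.07 ± 0.922 CPM for Cfd and 44.4 ± 0.294, 8.61 ± 6.25 and 11.8 ± 4.36 CPM for Cidec at AL, LC and RF (SD, n = 3, 4 and 3), although at RF against AL neither passed edgeR's test (adjusted p = 0.11 and 0.27; over the alternatives 6.0e-10, by DESeq2, to 0.41 for Cfd and 0.037 to 0.62 for Cidec). Adipose tissue in the AL samples could give this, but Adipoq, an abundant adipocyte transcript, had at most 1 count in every library, beside 713 to 1819 counts of Cfd at AL. Of the 8 adipocyte markers 4 were tested, and the median of Fabp4, Lpl and Adrb3, which liver also held and of which Fabp4 and Lpl stand in other lists, was 0.51 at LC against AL. A single high AL library is argued against for Cidec, a core gene fixed before, as 3 of 3 AL libraries (44.1 to 44.6 CPM) lay above all LC and RF libraries (at most 17.5 CPM); the same held for Cfd, but its naming required no overlap between AL and LC. The feeding cycle, the difference the design names, and reads shared with other genes stay open and were not tested.

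Fatty acid synthesis genes were higher as a list at RF than at AL, which may reflect refeeding beyond the control level, a single library or chance. Leaving out each RF library in turn kept the call. Camera called 10 to 21 lists in the other splits of the AL and RF samples, so a kept call cannot exclude a single RF library as the whole cause. The camera adjusted p was 0.028 without RF replicate 2, 6.2e-06 without RF replicate 1 and 6.2e-09 without RF replicate 3. Without AL replicate 2 it was 0.021. Sample quality weights gave 0.0026, but RF replicate 2 had a weight of 1.09. The weights thus did not reduce that library and cannot test what it carries. By library, the list's median over AL was 0.33, 0.95 and 0.18 at RF and −0.08, −0.06 and 0.32 at AL, so that RF replicate 2 alone stood clear of AL replicate 4, and how much of the difference it carries stays open. The adjusted p of 0.34 with an estimated correlation, the highest of the alternatives run, and 0.23 with fry leave genes that vary together by chance open. For the number of lists called at RF against AL the 10 splits of the 6 samples are too few for a share under 0.05, with 24 lists in the real split and at most 21 in the others.

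For RF against AL the 10 splits are also too few for the number of genes, with 7 in the real split, the 1 with as many, and 0 in the others. For RF against LC 1 of 35 splits, the real one, called as many genes (2821 against at most 412), which argues against chance. No smaller share was possible there either. For the number of lists chance cannot be excluded, since 4 of 35 splits gave as many as the 22 at LC against AL (at most 25 in the others), and 5 of 35 as many as the 18 at RF against LC (at most 20).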

How the results depend on the processing

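The removal of length and GC trends and the omission of the 50 most abundant genes were chosen after the data were seen. No result reversed past a threshold under any alternative run, while 117 values of genes taken by the naming rule or chosen later changed sign with no call in either setting. Of these genes, where called, 38 of 64 at LC against AL, 1 of 7 at RF against AL (Gm52512, which had no value with length and GC trends removed) and 24 of 55 at RF against LC were called in all alternatives. Leaving the stricter thresholds and the block aside, these were 54, 1 and 38.

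At LC against AL, 2045 genes were higher and 1989 lower. Library totals alone gave 4395 and 686, log2(FPKM + 1) 4291 and 708, log2(FPKM + 0.1) 4294 and 715, and the omission of the 50 most abundant genes, with library totals in place of TMM, 3147 and 1119; these settings lack the TMM factors, which were 0.827 to 0.952 at AL and 1.06 to 1.18 at LC. A log2 fold change of at least 1 left 486 and 332, and an adjusted p below 0.01 left 880 and 1050, by construction. Leaving out a library gave 959 to 2186 and 1151 to 2167.

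At RF against AL, 2 genes were higher and 5 lower. The counts were 39 and 61 with DESeq2, 20 and 30 with voom and sample weights, 4 and 1 with library totals alone, 5 and 8 with no filter on low counts, 1 and 0 with both FPKM offsets (1 and 0.1), 0 and 0 with length and GC trends removed and 1 and 0 at an adjusted p below 0.01. The omission of the 50 most abundant genes, with library totals in place of TMM, gave 1 lower, as many as library totals with all genes, and leaving out a library 1 to 4 higher and 0 to 10 lower. The cause was not tested.

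At RF against LC, 1452 were higher and 1369 lower. Library totals alone gave 673 and 2724, log2(FPKM + 1) 707 and 2782 and log2(FPKM + 0.1) 696 and 2681. A log2 fold change of at least 1 left 285 and 249, an adjusted p below 0.01 left 584 and 467, and leaving out a library gave 792 to 1604 and 643 to 1537.

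With the correlation estimated for each list, 0 lists were called higher and 0 lower in all 3 comparisons, against 1 and 21 at LC against AL, 6 and 18 at RF against AL and 17 and 1 at RF against LC. Fry called 2 higher at LC against AL, 1 higher and 0 lower at RF against AL, and 3 lower at RF against LC; a minimum of 1 CPM in 3 samples called 2 higher at LC against AL. Leaving out a library gave 0 to 2 and 20 to 23, 5 to 8 and 15 to 20, and 15 to 18 and 1 to 2 in that order. Of the genes called at LC, 5 were kept and 2215 returned. DESeq2 gave 60 kept, splits of the LC libraries a median of 2.5 kept and 1062.5 returned, a log2 fold change of at least 1 gave 334 returned, and leaving out a library 0 to 10 kept and 1240 to 2488 returned.

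Replicate numbers did not meet the bar for pairing, an r above 0.1 in every same-numbered pair. The 8 pairs had r of −0.046 to 0.252, with 2 above 0.1, both between LC and RF, where the pairs had 0.252, 0.185 and 0.049. There LC replicates 1, 2 and 3 each matched best with their own number, but RF replicate 3 with LC replicate 4 (0.117), a hint from the data, not the design. In 8 of 16 searches of another group the best match of a library carried its own number. With replicate number as a block the counts were 1957 higher and 1901 lower at LC against AL, 1 and 4 at RF against AL, 1613 and 1617 at RF against LC, with 4 kept and 2330 returned. At RF against AL, Krt23 and Tpm2 were called with the block, Asap2, Gsta2, Trib3 and Lgals1 were not (adjusted p = 0.073 to 0.16), and Gsta1 was (0.013), so 3 of the 5 kept genes named were not among the 4. Saa1, Ugt1a5, Aqp8 and Plin4 at LC against AL (0.058 to 0.13) and Arntl, Ugt1a5, Gadd45b, Csad and Aqp8 at RF against LC (0.051 to 0.080) were not called either. The block called 2 lists higher and 19 lower, 7 and 14, and 18 and 2 in the same order.

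Depth, at 13871500 to 15899500 counts, limits genes near 1 CPM such as Mki67 and Arntl. In simulations with few changed genes 4.48% to 7.46% of changes of 0.5 on the log2 scale were recovered, so a gene not called here can still differ by that much. These shares need not hold at LC against AL or RF against LC, where far more genes were called.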

Other observations

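No test in this part was chosen after its result was seen.

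At LC against AL, of 27 genes of xenobiotic metabolism 11 fell and 2 rose (11 and 2 adjusted over the list alone; list adjusted p = 0.0037, and adjusted p = 0.43 with an estimated correlation). Ugt2b1, a glucuronidation gene (−1.05), and the glutathione transferase gene Gstm3 (−1.36) fell, while Nr1i3, the gene of the drug-sensing receptor CAR, rose from 303 ± 46.5 CPM at AL (SD, n = 3) to 646 ± 59.0 CPM at LC (n = 4; 1.09, SE 0.14, adjusted p = 0.00030). Of 16 periportal hepatocyte genes 8 fell and none rose (9 adjusted over the list alone; median −0.62, list adjusted p = 1.0e-04, and adjusted p = 0.24 with an estimated correlation), and of 16 pericentral genes 7 fell and 3 rose (the same counts adjusted over the list alone; median −0.35, list adjusted p = 0.074, not called). With library totals alone these medians were −0.31 and −0.03. Of 26 genes of autophagy and the lysosome 13 fell and 2 rose (13 and 3 adjusted over the list alone; list adjusted p = 0.00013, and adjusted p = 0.36 with an estimated correlation). Of 20 NRF2 and antioxidant genes 8 fell and 1 rose (8 and 1 adjusted over the list alone; list adjusted p = 0.00060, and adjusted p = 0.33 with an estimated correlation). The medians of the xenobiotic, autophagy and NRF2 lists were −0.43, −0.47 and −0.41, and −0.10, −0.16 and −0.09 with library totals alone. Of 9 cholangiocyte markers 2 rose and none fell (2 adjusted over the list alone; list adjusted p = 0.33). Epcam was one of them (0.95), a call lost without AL replicate 2 (0.072) or AL replicate 3 (0.10).

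Class II, erythroid and cytokine lists were lower at LC against AL, and each lost its call without AL replicate 2. Of 8 class II antigen presentation genes 5 fell and none rose (6 adjusted over the list alone; list adjusted p = 0.024, and adjusted p = 0.47 with an estimated correlation), a call lost without AL replicate 2 (0.15) or LC replicate 2 (0.053). Of 5 erythroid genes 2 fell and none rose (2 adjusted over the list alone; list adjusted p = 0.026, and adjusted p = 0.47 with an estimated correlation), a call lost without AL replicate 2 (0.12). Of 16 cytokine and chemokine genes 4 fell and none rose (4 adjusted over the list alone; list adjusted p = 0.041, and adjusted p = 0.50 with an estimated correlation), with a median of −0.22 that turns to 0.07 with library totals alone, and the call was lost without AL replicate 2 (0.25), AL replicate 4 (0.058) or LC replicate 1 (0.079), with fry (0.057) and with a minimum of 1 CPM in 3 samples (0.076).

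At RF against AL no member of the following lists passed over all genes. Extracellular matrix genes were higher (median 0.32 over 26 genes, none passed adjusted over the list alone; list adjusted p = 0.00017, and adjusted p = 0.37 with an estimated correlation). The collagen gene Col4a2 was at 8.88 ± 1.88 CPM at AL and 14.4 ± 0.871 CPM at RF (SD, n = 3 each; 0.70, SE 0.20, adjusted p = 0.26), and Ccn2 had 1.18 (SE 0.36, adjusted p = 0.28). The list call was lost without RF replicate 2 (0.059). Interferon-stimulated genes were higher (median 0.29 over 26 genes, none passed adjusted over the list alone; list adjusted p = 0.0031, and adjusted p = 0.37 with an estimated correlation), with Stat2 at 0.68 (SE 0.20, adjusted p = 0.26), a list call lost without AL replicate 3 (0.071) or RF replicate 3 (0.068). Autophagy and lysosome genes were lower (median −0.23 over 26 genes, or −0.12 with library totals alone, 3 fell adjusted over the list alone; list adjusted p = 6.1e-06, and adjusted p = 0.28 with an estimated correlation). The glutathione transferase gene Gsta1, a close copy of the called Gsta2, had a log2 fold change of −2.30 (SE 0.38, adjusted p = 0.052; over the alternatives 8.8e-06, by DESeq2, to 0.24, without RF replicate 2).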
